A study of Mus musculus with 72 samples.

How the data were processed

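The series holds 72 samples from RAW264.7 mouse macrophage-like cells. Values were used from 9 RNA-seq and 9 ATAC-seq libraries, 3 each for the hairpins against GFP, NCOR and SMRT, and each library's group and number were taken from its title in the labels. The ATAC protocol in the labels describes wild-type cells seeded in triplicate wells whereas the titles name the hairpins, and the titles were followed. The 54 ChIP-seq and CUT&Tag samples were not analysed here.

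For RNA, the deposited values are RPKM, reads per kilobase of exon and M reads (M, mega). Per the file headers, HOMER counted reads over exons of mm10 RefSeq transcripts on both strands, with 1 transcript per gene. Reads of antisense or overlapping genes therefore cannot be told apart. For ATAC, the deposited values are reads per peak scaled to 10 M reads per library, and per the file headers HOMER annotated a merged peak list on mm10, without a stated shift of reads for the transposase. The submitters' processing notes name Bowtie2, HISAT2, HOMER, MACS2 and DESeq2 and the builds mm9 and mm10, without versions or roles. Which of them called the ATAC peaks is not given in the sources used here. The ATAC table writes decimal commas, which were read as points, and 1 of its cells held no number, so that peak was left out.

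The RNA table held 25124 genes, of which 9005 were listed at 0 in all 9 libraries, and the table of accessibility listed 51984 peaks with a median width of 366 bp. Values were whole multiples of 1 read, to within 0.1 read, for 100% of the values tested, which gave the depth of each library: 39.1 to 49.1 M reads in RNA and 6.06 to 10.84 M in ATAC. No pair of libraries in a group agreed within sampling noise (chi-square per feature 1.64 to 10.5), so each was counted as 1 library.

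Tests were made on log2(RPKM + 1) for the 10789 genes with at least 1 RPKM in at least 3 of 9 libraries, and on log2(value + 5) for the 51469 peaks with a value of at least 10 in at least 3 libraries. All 9 libraries of an assay entered 1 limma fit (version 3.58.1, R 4.3.3) with a mean-variance trend, and calls were made at a Benjamini-Hochberg adjusted p under 0.05 in each of the 3 contrasts. The 23 gene lists, 20 of them with at least 5 tested members in RNA, were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists. Of the listed symbols, 2 were not in the RNA table. For ATAC, peaks within 50 kb of the start site of a member were tested in the same way. The lists were corepressor complex subunits, LXR targets, fatty acid synthesis, cholesterol synthesis, inflammatory, interferon-stimulated, alternative activation, PPAR target, macrophage identity, lysosome, osteoclast, dendritic cell, neutrophil and mast cell, lymphocyte, fibroblast and epithelial, proliferation, stress response, hypoxia, oxidative phosphorylation, antioxidant, complement, ribosomal and histone genes. The tests, lists, alternatives and rule for named genes were fixed before the data were examined. A fold change on this scale understates the change of low genes.

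Genes named are Ncor1, the 10 called genes with the largest and the 10 with the smallest log2 fold change against shGFP whose groups did not overlap (5 each between the knockdowns), leaving out unnamed and small RNA genes, and up to 4 members per list, the 2 called ones with the largest and the 2 with the smallest log2 fold change. Some genes that the rule names are not reported here, and Ccl5 and Fth1 were left out after their calls were seen to end under other settings. For ATAC the 5 most raised and 5 most lowered peaks per knockdown are named, and the peak nearest to the start site of a named gene. Other genes named in the closing section were chosen after their values were seen. In simulated data with 200 changed features, the ATAC fit recovered 28.4%, 77.6% and 93.9% of peaks changed 1.5, 2 and 3 fold in shNCOR against shGFP among 51469 peaks, and the RNA fit 100%, 100% and 100% among 10789 genes. The changed features were drawn only from those well above the filter minimum in shGFP. All features of an assay were given 1 dispersion, so recovery of weak or variable features may be lower.

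Alternatives were other pseudocounts, filters, scalings, a replicate block, fits on 6 libraries, array weights, a fold threshold, leaving out each library, other windows around genes and an estimated correlation. A limma voom fit on the recovered reads and removal of the trend with exon length were added after seeing the data. Count models such as DESeq2 were not run, because the values were deposited in scaled units, although reads could be recovered from them. Figures were drawn with matplotlib 3.10.9.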

Results

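RAW264.7 cells, a mouse macrophage-like line, had been infected with lentivirus carrying a short hairpin RNA against GFP (the control, shGFP), NCOR (shNCOR) or SMRT (shSMRT). NCOR, encoded by Ncor1, and SMRT are corepressors that bring the histone deacetylase HDAC3 to nuclear receptors and other transcription factors. RNA was sequenced from 9 libraries and chromatin accessibility was measured by ATAC-seq in another 9, with 3 libraries per group in each assay. The other 54 samples of the series, from ChIP-seq and CUT&Tag, were not analysed here. The RNA libraries held 39.1 to 49.1 M reads, of which 90.9 to 92.8% lay in exons of the table. The ATAC libraries held 6.06 to 10.84 M reads, and the share of reads in peaks was 53.5, 50.1, 52.7% in shGFP, 54.1, 54.9, 54.8% in shNCOR and 47.2, 49.4, 48.9% in shSMRT. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

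The hairpin against NCOR lowered Ncor1, and the hairpin against SMRT left it uncalled. Ncor1 (chr11, 62316426 to 62438515, mm10) was at 19.1 ± 0.973 RPKM in shGFP (SD, n = 3), 4.04 ± 0.372 in shNCOR and 19.8 ± 0.748 in shSMRT. Its log2 fold change against shGFP was -2.00 ± 0.06 (SE) in shNCOR (limma, adjusted p = 8.89e-10) and 0.05 ± 0.06 in shSMRT (adjusted p = 0.494). Of the subunits that join the corepressors, Tbl1xr1 rose in both knockdowns (0.51 ± 0.05 in shNCOR and 0.40 ± 0.05 in shSMRT), as did Coro2a (0.68 ± 0.06 and 0.31 ± 0.06), and Hdac3 fell slightly (-0.13 ± 0.03 and -0.17 ± 0.03). The ATAC peak at the Ncor1 promoter says nothing about RNA knockdown and does not check the ATAC labels.

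**Figure D1:**
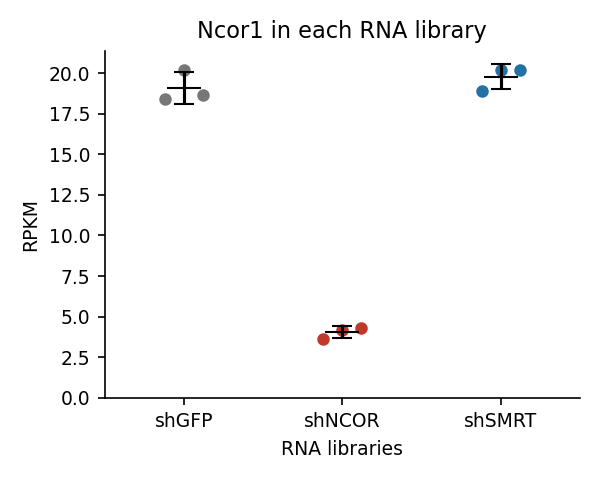
RPKM of Ncor1 in each of the 9 RNA libraries by group. Points are libraries, the dash is the mean and the bar the SD (n = 3). Ncor1 was lower in the shNCOR libraries.

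The first comparison asked what differed between shNCOR and shGFP. In neither comparison with shGFP can loss of the target be told apart from another difference between the separately infected cell populations. Interferon-stimulated genes fell together in shNCOR. All 29 tested members of the list were lower, with a median log2 fold change of -1.54 (SD 0.81 over members). Rtp4, an interferon-induced gene, went from 19.9 ± 1.78 RPKM in shGFP to 0.603 ± 0.122 in shNCOR (-3.70 ± 0.08, adjusted p = 9.28e-11), and Ifi44 from 25.5 ± 0.837 to 1.71 ± 0.288 (-3.30 ± 0.08). Against this, the retinoic acid receptor gene Rarb rose from 0.689 ± 0.174 to 10.5 ± 0.114 RPKM (2.77 ± 0.10, adjusted p = 3.9e-09).

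Other genes that rose most in shNCOR were Ranbp3l (2.40 ± 0.10), the chemokine receptor gene Cxcr4 (2.33 ± 0.07), Atp6v0d2, a vacuolar ATPase subunit of osteoclasts (2.10 ± 0.06), and the lymphatic growth factor gene Vegfc (1.87 ± 0.09). Next came Opcml (1.79 ± 0.07), the macrophage elastase Mmp12 (1.75 ± 0.07), the tartrate-resistant phosphatase Acp5 (1.68 ± 0.05), the beta-glucan receptor Clec7a (1.67 ± 0.05) and the carbonic anhydrase Car2 (1.66 ± 0.04). Car2 was abundant, at 190.4 ± 8.26 RPKM in shGFP and 605 ± 13.3 in shNCOR. Besides Rtp4 and Ifi44, the genes that fell most included the high-affinity IgG receptor Fcgr1 (-3.71 ± 0.05, from 17.4 ± 0.112 to 0.416 ± 0.0687 RPKM) and the neighbouring genes Tmem176b (-3.54 ± 0.05) and Tmem176a (-3.07 ± 0.08). They also included Ifi44l (-3.27 ± 0.14), lymphotoxin beta Ltb (-2.98 ± 0.08), the MHC class I-like H2-T24 (-2.88 ± 0.08), Rnase4 (-2.83 ± 0.06) and Ifi27l2a (-2.77 ± 0.06). H2-T24 belongs to a family of near-identical genes, Ifi44 and Ifi44l are related, and Rnase4 shares exons with a neighbour, so reads could be split among them. Fold changes were computed on RPKM plus 1, which understates the change of weakly expressed genes such as Rarb and Ranbp3l.

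By list, 0 of 29 tested interferon-stimulated genes rose and 29 fell (camera, adjusted p = 2.61e-27, and 0.0233 with an estimated correlation). Of the PPAR target genes, 14 of 19 tested members rose and 2 fell (adjusted p = 3.01e-06, and 0.0293 with an estimated correlation). Plin2, which coats lipid droplets, was at 1.31 ± 0.04, the scavenger receptor Cd36 at 1.05 ± 0.04 and Pparg itself at -0.55 ± 0.10. Of the proliferation genes, 0 of 28 tested members rose and 18 fell (adjusted p = 3.01e-06, and 0.0293 with an estimated correlation). The cyclins Ccnb1 (-0.30 ± 0.03) and Ccnb2 (-0.29 ± 0.04) were among them. Of the lysosome genes, 21 of 25 tested members rose and 1 fell (adjusted p = 4.38e-09, and adjusted p = 0.0777 with an estimated correlation). The cathepsins Ctsl (0.80 ± 0.03) and Ctsd (0.62 ± 0.03) rose. Among osteoclast genes, 10 of 15 tested members rose and 1 fell (adjusted p = 0.000141, and adjusted p = 0.0703 with an estimated correlation). Atp6v0d2 and Acp5 rose most and Ocstamp fell (-0.78 ± 0.09). For LXR target genes, 8 of 17 tested members rose and 2 fell (adjusted p = 0.0311, and adjusted p = 0.269 with an estimated correlation). The cholesterol exporter Abca1 was at 1.24 ± 0.07 and Smpdl3a at 0.84 ± 0.07. The fatty acid list moved the other way, as 3 of 17 tested members rose and 9 fell (adjusted p = 0.0311, and adjusted p = 0.269 with an estimated correlation). The elongase Elovl5 was at -0.52 ± 0.03 and the desaturase Scd1 at -0.49 ± 0.04. In the cholesterol list 2 of 24 tested members rose and 12 fell (adjusted p = 0.0335, and adjusted p = 0.472 with an estimated correlation). Tm7sf2, 1 of those that rose, was at 0.44 ± 0.09. In the hypoxia and glycolysis list 1 of 21 tested members rose and 9 fell (adjusted p = 0.0311, and adjusted p = 0.472 with an estimated correlation). The glucose transporter Slc2a1 was at -0.35 ± 0.04.

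Lists not called in shNCOR were the corepressor complex subunits (3 higher and 2 lower of 7, adjusted p = 0.556), the NF-kB and AP-1 inflammatory genes (8 higher and 12 lower of 25, adjusted p = 0.618) and the IL-4 and alternative activation genes (4 higher and 3 lower of 12, adjusted p = 0.467). Also not called were the monocyte and macrophage identity genes (9 higher and 8 lower of 24, adjusted p = 0.631), the dendritic cell and MHC class II genes (2 higher and 3 lower of 6, adjusted p = 0.695) and the integrated stress and unfolded protein response (6 higher and 12 lower of 24, adjusted p = 0.198). The same holds for the oxidative phosphorylation genes (5 higher and 1 lower of 23, adjusted p = 0.225), the antioxidant and NRF2 target genes (4 higher and 3 lower of 17, adjusted p = 0.66) and the complement and phagocytosis genes (7 higher and 4 lower of 14, adjusted p = 0.198). Nor was a call made for the ribosomal protein and RNA quality genes (1 higher and 4 lower of 22, adjusted p = 0.618) and the replication-dependent histone genes (2 higher and 0 lower of 5, adjusted p = 0.32). Adjusted over the list alone, the counts were 9 higher and 3 lower for LXR target genes, 5 higher and 11 lower for fatty acid synthesis and desaturation and 4 higher and 4 lower for IL-4 and alternative activation genes. In the same way they were 10 higher and 8 lower for monocyte and macrophage identity genes, 10 higher and 2 lower for osteoclast genes and 11 higher and 12 lower for integrated stress and unfolded protein response. They were also 1 higher and 11 lower for hypoxia and glycolysis genes, 5 higher and 0 lower for oxidative phosphorylation genes and 8 higher and 5 lower for complement and phagocytosis genes. They were further 1 higher and 1 lower for ribosomal protein and RNA quality genes. They equalled the counts over all genes for the other lists. Within those lists single members still moved, including the integrin Itgax (1.53 ± 0.05), the transglutaminase Tgm2 (1.56 ± 0.07), Gas6 (1.40 ± 0.06) and, downward, Klf4 (-1.52 ± 0.08), Flt1 (-1.47 ± 0.08), Plaur (-0.98 ± 0.03) and Cd74 (-0.81 ± 0.04). No neutrophil or mast cell gene and 1 lymphocyte and 1 fibroblast or epithelial gene passed the filter on low values, so those lists were not tested in RNA, and Lck (0.25 ± 0.12) and Tagln (-0.03 ± 0.08) were not called.

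Over all 10789 tested genes, 1895 were higher and 2161 lower in shNCOR than in shGFP (limma, Benjamini-Hochberg adjusted p under 0.05), of which 52 and 113 changed by at least 1 on the log2 scale. For 3975 called genes the libraries of the groups did not overlap, and 48.1% of all tested genes had non-overlapping groups, where chance gives 10%. The calls on the cholesterol list ended under quantile normalization (adjusted p = 0.0609) and without shNCOR replicate 2 (0.0515) or replicate 3 (0.105). The call on the hypoxia list ended without shGFP replicate 1 (0.0607) or shNCOR replicate 2 (0.103). Both ended with the exon length trend removed, an alternative chosen after seeing the data (0.062 and 0.0756).

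The second comparison asked what differed between shSMRT and shGFP. Hpgd, which encodes the enzyme that inactivates prostaglandins, rose from 0.632 ± 0.108 RPKM in shGFP to 60.9 ± 1.84 in shSMRT (5.25 ± 0.09, adjusted p = 1.14e-11). Inflammatory and osteoclast genes rose, including the monocyte chemoattractant Ccl2 (6.69 ± 0.561 to 79.9 ± 6.60 RPKM, 3.40 ± 0.07), Atp6v0d2 (3.46 ± 0.06) and Acp5 (2.81 ± 0.05). Genes of proliferation fell, and so did those of cholesterol and fatty acid synthesis (adjusted p = 0.0612 and 0.0508 with an estimated correlation). The desaturase Scd1 went from 59.8 ± 1.24 to 19.1 ± 0.627 RPKM (-1.60 ± 0.04, adjusted p = 1.59e-10).

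Further genes that rose most in shSMRT were Mmp12 (3.42 ± 0.07), the integrin Itgax, also called CD11c (3.35 ± 0.05), the metallothionein Mt3 (3.08 ± 0.11), the matrix protein tenascin C gene Tnc (2.99 ± 0.08), lysozyme Lyz1 (2.86 ± 0.04) and Uchl1 (2.81 ± 0.12). Lyz1 was at 395 ± 5.49 RPKM in shGFP and 2871 ± 139 in shSMRT, and its reads may be shared with the closely related Lyz2. Mt3 and Tnc were near 0 in shGFP (0.0290 ± 0.0502 and 0.0383 ± 0.0310 RPKM). The genes that fell most were Tmem176b (-2.21 ± 0.05), Tmem176a (-1.87 ± 0.08), Scd1 and Ifi27l2a (-1.48 ± 0.06). Next came the troponin gene Tnni2 (-1.46 ± 0.08), the tetraspanin Cd81 (-1.41 ± 0.08), Fam13c (-1.40 ± 0.07), Cd300e (-1.37 ± 0.09), Calhm6 (-1.36 ± 0.11) and Ambp (-1.36 ± 0.10).

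Among NF-kB and AP-1 inflammatory genes, 20 of 25 tested members rose and 3 fell in shSMRT (median log2 fold change 0.42, SD 0.99 over members, camera, adjusted p = 1.3e-08, and 0.01 with an estimated correlation). Jun was lower (-0.34 ± 0.04). Of the osteoclast genes, 12 of 15 tested members rose and 2 fell (median log2 fold change 1.12, SD 1.21 over members, adjusted p = 5.25e-07, and 0.0217 with an estimated correlation), and Car2 was lower (-1.04 ± 0.04). Of the macrophage identity genes, 18 of 24 tested members rose and 4 fell (adjusted p = 4.64e-06, and 0.0112 with an estimated correlation). Fcgr3 was at 1.12 ± 0.04 and Fcgr1 at -0.86 ± 0.05. For proliferation genes, 0 of 28 tested members rose and 25 fell (adjusted p = 9.48e-09, and 0.01 with an estimated correlation). Birc5 (-0.70 ± 0.04) and Tyms (-0.55 ± 0.04) are examples. Of the interferon-stimulated genes, 2 of 29 tested members rose and 21 fell (median log2 fold change -0.43, SD 0.42 over members, adjusted p = 0.000158, and adjusted p = 0.134 with an estimated correlation). Rtp4 was at -1.14 ± 0.08 and Cxcl10 at 0.51 ± 0.10. In the cholesterol list 0 of 24 tested members rose and 20 fell (adjusted p = 2.85e-06, and adjusted p = 0.0612 with an estimated correlation). The reductase Dhcr7 (-0.97 ± 0.03) and Fdps (-0.80 ± 0.04) were among them. The fatty acid list gave 1 of 17 members that rose and 12 that fell (adjusted p = 7.35e-05, and adjusted p = 0.0508 with an estimated correlation), Fads2 being at -0.78 ± 0.03. For the stress and unfolded protein response 4 of 24 tested members rose and 18 fell (adjusted p = 2.93e-05, and adjusted p = 0.0508 with an estimated correlation). Trib3 (-1.04 ± 0.14) and Chac1 (-0.88 ± 0.08) fell and Atf3 (0.56 ± 0.04) rose.

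Lysosome genes again moved mostly upward, as 17 of 25 tested members rose and 3 fell (adjusted p = 5.23e-06, and adjusted p = 0.0847 with an estimated correlation), Ctsl at 0.83 ± 0.03 and Lamp1 at -0.32 ± 0.02. In the alternative activation list 8 of 12 tested members rose and 3 fell (adjusted p = 0.00278, and adjusted p = 0.0629 with an estimated correlation). The transcription factor Egr2 was at 2.74 ± 0.06 and Clec7a at 2.16 ± 0.05. In the complement and phagocytosis list 11 of 14 tested members rose and 3 fell (adjusted p = 0.000125, and adjusted p = 0.0508 with an estimated correlation), with Cd36 at 1.87 ± 0.04. Of the dendritic cell and MHC class II list 4 of 6 tested members rose and 2 fell (adjusted p = 0.0146, and adjusted p = 0.0745 with an estimated correlation). The members that rose there, such as Itgax and the costimulatory Cd80 (1.68 ± 0.07), are activation and adhesion genes, while the class II chaperone Cd74 was lower (-0.51 ± 0.04). For replication-dependent histones 4 of 5 tested members rose and 0 fell (adjusted p = 0.0146, and adjusted p = 0.0745 with an estimated correlation), led by Hist2h2aa1 (2.25 ± 0.14), which has a near-identical copy. In the hypoxia list 2 of 21 tested members rose and 14 fell (adjusted p = 0.0074, and adjusted p = 0.275 with an estimated correlation), Vegfa being at -1.09 ± 0.12. In the oxidative phosphorylation list 0 of 23 tested members rose and 17 fell (adjusted p = 4.25e-05, and adjusted p = 0.275 with an estimated correlation), Atp5o and Uqcrc2 being at -0.37 ± 0.03 and -0.36 ± 0.03. Across genes, fold changes in shSMRT rose with exon length (Spearman rho 0.160 over 10789 genes, which are not independent replicates), against 0.0360 in shNCOR. Lists not called were the corepressor complex subunits (2 higher and 2 lower of 7, adjusted p = 0.934), the LXR target genes (8 higher and 4 lower of 17, adjusted p = 0.118) and the PPAR target genes (10 higher and 6 lower of 19, adjusted p = 0.102). Also not called were the antioxidant and NRF2 target genes (8 higher and 5 lower of 17, adjusted p = 0.118) and the ribosomal protein and RNA quality genes (3 higher and 7 lower of 22, adjusted p = 0.934). Adjusted over the list alone, the counts were 9 higher and 4 lower for LXR target genes, 10 higher and 7 lower for PPAR target genes and 19 higher and 4 lower for monocyte and macrophage identity genes. In the same way they were 0 higher and 26 lower for proliferation genes, 5 higher and 18 lower for integrated stress and unfolded protein response and 4 higher and 1 lower for replication-dependent histone genes. They equalled the counts over all genes for the other lists. Heme oxygenase Hmox1 (1.17 ± 0.03) was higher within the antioxidant list.

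In all, 2630 genes were higher and 3386 lower in shSMRT than in shGFP, of which 156 and 40 changed by at least 1 on the log2 scale. Non-overlapping groups were seen for 5877 of the called genes and 63.1% of all tested genes. The PPAR target and antioxidant lists, not called here, passed under quantile normalization (adjusted p = 0.0459 and 0.0215). With the exon length trend removed, an alternative chosen after seeing the data, the lists called in shSMRT kept their calls. The PPAR target list passed in that setting (camera, adjusted p = 0.0432).

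**Figure D2:**
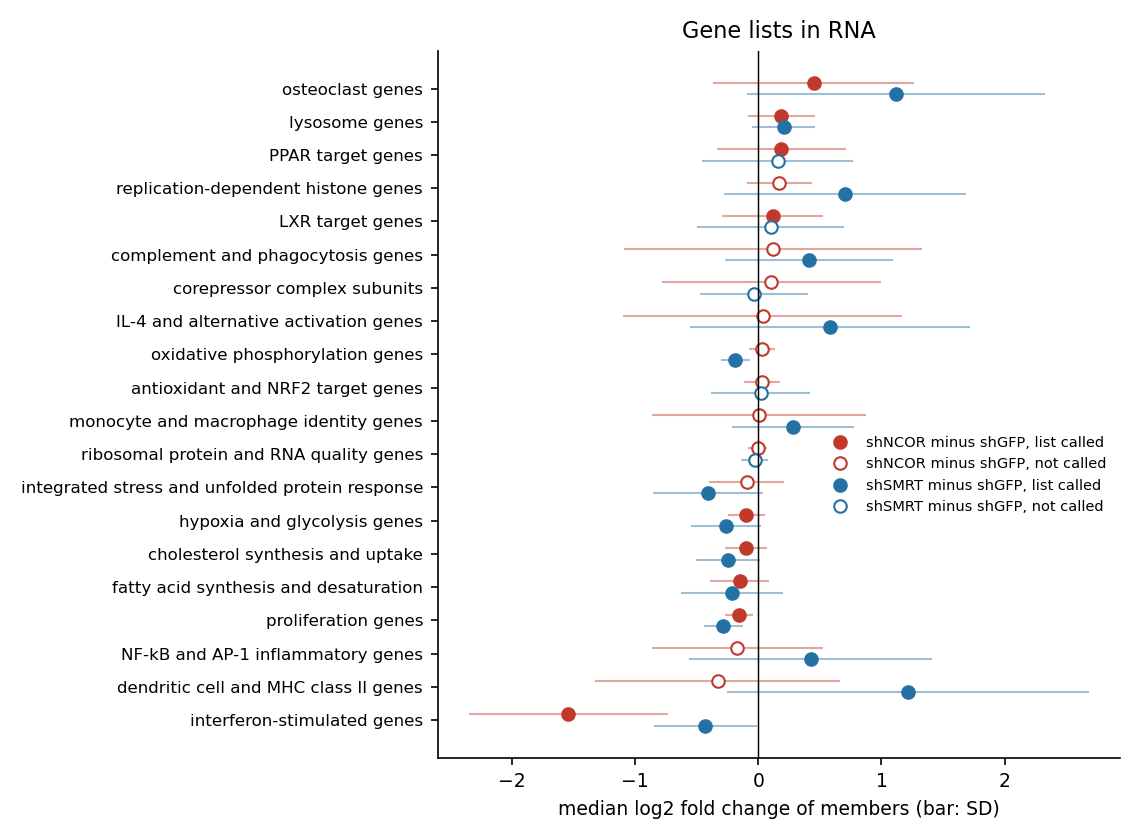
Median log2 fold change of the tested members of each gene list against shGFP in shNCOR (red) and shSMRT (blue), with bars of SD over members. Filled points are lists called at adjusted p under 0.05. Interferon-stimulated genes had a median of -1.54 in shNCOR and -0.43 in shSMRT.

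The knockdowns were then compared with each other. Interferon-stimulated genes stood higher in shSMRT than in shNCOR for 29 of 29 members (median log2 fold change 1.23, SD 0.59 over members, adjusted p = 1.69e-19, and 0.0186 with an estimated correlation). Hpgd (5.03 ± 0.09), the angiopoietin-like gene Angptl2 (3.34 ± 0.06), Mt3 (3.02 ± 0.11), Tnc (2.90 ± 0.08) and the G-protein regulator Rgs16 (2.89 ± 0.07) were the genes most raised in shSMRT over shNCOR. Car2 (-2.70 ± 0.04), Rarb (-2.57 ± 0.10), Ranbp3l (-2.55 ± 0.10), Opcml (-2.13 ± 0.07) and Gas6 (-1.72 ± 0.06) were the most lowered. Car2 was at 605 ± 13.3 RPKM in shNCOR and 92.1 ± 2.51 in shSMRT.

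Of the inflammatory genes, 21 of 25 tested members rose and 1 fell in shSMRT against shNCOR (adjusted p = 6.3e-12, and 0.00662 with an estimated correlation), and of macrophage identity genes 19 of 24 tested members rose and 1 fell (adjusted p = 1.05e-07, and 0.00762 with an estimated correlation). Osteoclast genes (11 of 15 tested members rose and 3 fell, adjusted p = 2.94e-05, and 0.0286 with an estimated correlation), complement and phagocytosis genes (10 of 14 tested members rose and 1 fell, adjusted p = 2.71e-05, and 0.0286 with an estimated correlation), alternative activation genes (9 of 12 tested members rose and 1 fell, adjusted p = 0.000169, and 0.0286 with an estimated correlation) and the dendritic cell list (4 of 6 tested members rose and 0 fell, adjusted p = 0.000753, and 0.0286 with an estimated correlation) were also higher. Examples are Ctsk at 1.94 ± 0.11 and Egr2 at 1.22 ± 0.06. Proliferation genes (1 of 28 tested members rose and 18 fell, adjusted p = 0.000169, and 0.0286 with an estimated correlation), the cholesterol list (0 of 24 tested members rose and 17 fell, adjusted p = 2.94e-05, and adjusted p = 0.076 with an estimated correlation), the fatty acid list (2 of 17 tested members rose and 11 fell, adjusted p = 0.003, and adjusted p = 0.0821 with an estimated correlation), the stress response list (3 of 24 tested members rose and 17 fell, adjusted p = 0.000145, and adjusted p = 0.0509 with an estimated correlation) and oxidative phosphorylation (0 of 23 tested members rose and 21 fell, adjusted p = 1.79e-07, and adjusted p = 0.211 with an estimated correlation) were lower. For histones 3 of 5 tested members rose and 0 fell (adjusted p = 0.0456, and adjusted p = 0.114 with an estimated correlation). That call ended under quantile normalization (adjusted p = 0.0511) and without shNCOR replicate 2 (0.067) or shSMRT replicate 2 (0.0754). Lists not called were the corepressor complex subunits (1 higher and 4 lower of 7, adjusted p = 0.184), the LXR target genes (6 higher and 8 lower of 17, adjusted p = 0.93) and the PPAR target genes (5 higher and 12 lower of 19, adjusted p = 0.0933). Also not called were the lysosome genes (8 higher and 7 lower of 25, adjusted p = 0.605), the hypoxia and glycolysis genes (5 higher and 10 lower of 21, adjusted p = 0.126) and the antioxidant and NRF2 target genes (8 higher and 3 lower of 17, adjusted p = 0.0615). The same holds for the ribosomal protein and RNA quality genes (4 higher and 4 lower of 22, adjusted p = 0.537). Adjusted over the list alone, the counts were 0 higher and 18 lower for cholesterol synthesis and uptake, 22 higher and 1 lower for NF-kB and AP-1 inflammatory genes and 12 higher and 3 lower for osteoclast genes. In the same way they were 5 higher and 0 lower for dendritic cell and MHC class II genes, 4 higher and 17 lower for integrated stress and unfolded protein response and 5 higher and 11 lower for hypoxia and glycolysis genes. They were also 3 higher and 2 lower for ribosomal protein and RNA quality genes. They equalled the counts over all genes for the other lists. The antioxidant list passed under quantile normalization (adjusted p = 0.00607) and without shNCOR replicate 1 (0.0447), and the lysosome list under quantile normalization (0.036). Altogether 2465 genes were higher and 3125 lower.

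Both knockdowns changed many genes against the same shGFP libraries. Atp6v0d2, Mmp12, Acp5 and Clec7a were called higher in both, and Tmem176b, Tmem176a and Ifi27l2a lower in both. In all, 1084 genes were higher in both and 1234 lower in both, where independent lists of those sizes would share 462 and 678. Another 559 genes were called in opposite directions, among them Car2 and Gas6. The covariance of fold changes was 0.0454, against 0.00281 in 20 simulations of unchanged groups with shared controls. The correlation was 0.445, against 0.501 simulated. The simulated groups shared 0 higher and 0 lower calls, but unchanged groups leave almost no calls to share. That 0 therefore cannot show how many shared calls the common controls create. With 3 control libraries no split into parts of 2 or more was possible, so part of the excess may come from the shared controls.

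**Figure D3:**
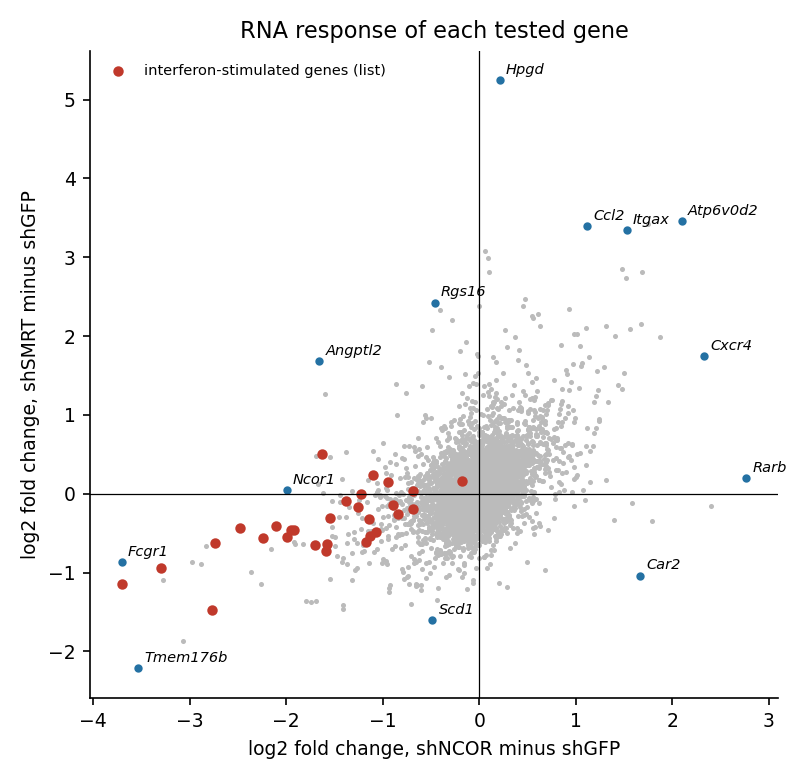
Log2 fold change of RPKM plus 1 against shGFP in shNCOR (horizontal) and shSMRT (vertical), 1 point per tested gene, with interferon-stimulated genes in red and named genes in blue. Most interferon-stimulated genes lie further below 0 on the shNCOR axis than on the shSMRT axis, and Hpgd and Rarb lie near 1 axis each.

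Accessibility asked where chromatin opened or closed. In shNCOR, peaks opened at Rarb and Abca1 and closed at Tmem176b and near interferon-stimulated genes. The Rarb promoter peak (chr14, 16575333 to 16575757, mm10) had 34.1 ± 10.4 normalised reads in shGFP (SD, n = 3) and 159 ± 31.1 in shNCOR (log2 fold change 2.08 ± 0.22 SE, limma adjusted p = 7.1e-10). The Tmem176b promoter peak (chr6, 48840501 to 48841555) went from 122 ± 13.5 to 15.0 ± 4.96 (-2.70 ± 0.28). Promoter peaks of Rtp4 (-0.80 ± 0.19) and Ifi44 (-1.47 ± 0.34) were lower, and those of Cxcr4 (0.86 ± 0.18), Atp6v0d2 (1.67 ± 0.16), Ccl2 (0.54 ± 0.09) and Abca1 (0.59 ± 0.13) higher. The tested peak nearest to the start site was also called higher at Opcml (1.14 ± 0.14), whose RNA rose. It was called lower at Fcgr1 (-0.62 ± 0.12), Rnase4 (-0.99 ± 0.18), H2-T24 (-0.72 ± 0.12) and Ifi27l2a (-0.71 ± 0.19), whose RNA fell. Some other genes with large RNA changes had a nearest peak that was not called. These were Ranbp3l (0.32 ± 0.18, adjusted p = 0.29), Vegfc (0.95 ± 0.38, adjusted p = 0.118), Mmp12 (0.43 ± 0.36, adjusted p = 0.524), Acp5 (0.45 ± 0.21, adjusted p = 0.183), Clec7a (0.67 ± 0.23, adjusted p = 0.0575) and Car2 (0.34 ± 0.13, adjusted p = 0.0839), which rose in RNA, and Ltb (-0.08 ± 0.16, adjusted p = 0.834), which fell. The Ranbp3l and Acp5 peaks lay 24416 and 4721 bp from the start site. Those of Mmp12 and Vegfc were weak, at 12.6 ± 6.94 and 8.37 ± 2.78 normalised reads in shGFP.

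The peaks most raised in shNCOR, each given with the nearest gene, lay by Ranbp3l (chr15, 8940839 to 8941319, intergenic, 2.94 ± 0.35), 9130008F23Rik (chr17, 40890173 to 40890601, intergenic, 2.19 ± 0.31), Olfm3 (chr3, 115284570 to 115284880, intergenic, 2.18 ± 0.31), Col14a1 (chr15, 55431179 to 55431499, intron, 2.13 ± 0.32) and Abca1 (chr4, 53149737 to 53150039, intron, 2.10 ± 0.30). Those most lowered lay nearest to Mdga2 (chr12, 66796053 to 66796493, intron, -3.75 ± 0.26), Cbfa2t3 (chr8, 122699106 to 122699571, promoter, -3.02 ± 0.29), Ppp1r26 (chr2, 28387453 to 28387795, intergenic, -3.00 ± 0.43) and Adam6b (chr12, 113424305 to 113425395, intergenic, -2.99 ± 0.29), and the list also held a peak on an unplaced chromosome 1 contig with no gene name. Over 51469 tested peaks, 2357 were higher and 2057 lower in shNCOR, with 4234 called peaks whose groups did not overlap (25.9% of all tested peaks, chance 10%). Lower peaks were the more numerous under quantile normalization (1643 higher and 2020 lower), with median centring (1982 higher and 2242 lower), without shNCOR replicate 3 (1662 higher and 2094 lower) and without shGFP replicate 2. Without shGFP replicate 1, 2 or 3, the lower calls numbered 1209, 1316 and 1156, and the higher calls without shGFP replicate 2 numbered 1228. The library labelled shNCOR replicate 2 was the shallowest (6.06 M reads) and stood apart on the third principal component (56.4, the other libraries between -38.5 and 11.1), and without it 1768 peaks were higher and 1640 lower.

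In shSMRT, accessibility rose at Atp6v0d2 (2.04 ± 0.16), Ccl2 (0.78 ± 0.09) and Itgax (0.41 ± 0.11) and fell at Tmem176b (-2.47 ± 0.28), Scd1 (-1.16 ± 0.14) and Car2 (-0.82 ± 0.13), each at the peak nearest to the start site. Nearest peaks were also called higher at Tnc (1.86 ± 0.50), Lyz1 (1.46 ± 0.16) and Mt3 (0.97 ± 0.28). They were called lower at Fam13c, Calhm6, Cd300e, Tnni2, Ambp and Ifi27l2a. The Tnc peak lay in an intron, 37054 bp from the start site. It was weak, at 2.18 ± 2.36 normalised reads in shGFP and 20.4 ± 5.34 in shSMRT. Peaks of Mt3, Cd300e and Ambp lay -1518, 2031 and 2634 bp from their start sites. The tested peak nearest to the Hpgd start site lay 5054 bp inside the gene and was not called (0.67 ± 0.27, adjusted p = 0.0812). Nor were those of Mmp12 (0.62 ± 0.36, adjusted p = 0.239), Acp5 (0.14 ± 0.21, adjusted p = 0.6965), Uchl1 (-0.27 ± 0.36, adjusted p = 0.6635) and Cd81 (-0.84 ± 0.34, adjusted p = 0.0802). The Uchl1 and Cd81 peaks lay -13029 and -9616 bp from the start site. The peaks most raised lay nearest to Mir148a (chr6, 51170917 to 51171214, intergenic, 3.47 ± 0.30), Maf (chr8, 115650153 to 115650610, intergenic, 3.00 ± 0.36), Prdm1 (chr10, 44518621 to 44519034, intergenic, 2.94 ± 0.42), Tnfsf8 (chr4, 63870475 to 63871084, intergenic, 2.89 ± 0.37) and Mir1896 (chr13, 21446854 to 21447105, transcript end, 2.85 ± 0.42). The peaks most lowered lay nearest to Lrpap1 (chr5, 35166036 to 35166448, intergenic, -3.06 ± 0.40), Mir383 (chr8, 37886685 to 37887149, intron, -2.67 ± 0.23), BC039966 (chr4, 153862320 to 153862587, intergenic, -2.57 ± 0.39), 1700008K24Rik (chr17, 49029884 to 49030204, intron, -2.56 ± 0.38) and Mir383 (chr8, 37901710 to 37902147, intron, -2.56 ± 0.23).

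In shSMRT 3506 peaks were higher and 5595 lower than in shGFP, so 61.5% of calls were lower, against 43.3% after quantile normalization (4390 higher and 3358 lower). Among changes of at least 1 on the log2 scale, 1627 peaks were higher and 497 lower. Without shGFP replicate 1 or replicate 3 the lower calls numbered 2710 and 3232. Against shNCOR, 3565 peaks were higher and 8999 lower in shSMRT, a lower share of 71.6% that became 40.3% after quantile normalization (2401 lower). The median log2 fold change of all tested peaks was -0.12 in that comparison and -0.03 after quantile normalization. Carbonic anhydrase Car2 (-1.16 ± 0.13) and Rarb (-2.02 ± 0.22) were less accessible and Angptl2 (1.66 ± 0.14) more accessible in shSMRT than in shNCOR. On the authors' scaling, the nearest peaks of Ctsk (-0.57 ± 0.17) and Hist2h2aa1 (-0.39 ± 0.14) were lower there while their RNA was higher (1.94 ± 0.11 and 1.71 ± 0.14). Against shGFP the same held in shSMRT for Atf3 (peak -0.30 ± 0.08, RNA 0.56 ± 0.04) and Hist1h2bc (peak -0.36 ± 0.08, RNA 1.45 ± 0.09). The Ctsk peak was annotated as a transcript end, the others as promoters. Promoters were in excess among lower peaks in shSMRT, and that excess was much smaller after quantile normalization, as given below. These single peaks were not retested with that scaling. A change specific to these promoters therefore cannot be told apart from the wider shift.

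Promoters and distal sites differed. Of the peaks lower in shSMRT than in shGFP 37.3% were annotated as promoter, of those higher 3.99%, and of uncalled peaks 16.4% (Fisher's exact test over peaks, which are not replicates: odds ratio 3.02 for lower and 0.211 for higher peaks). After quantile normalization the odds ratio of lower peaks was 1.17, and that of higher peaks 0.261. Against shNCOR the odds ratio of lower peaks went from 5.67 to 1.15. In shNCOR, promoters made up 11.9% of higher and 6.37% of lower peaks, against 18.7% of uncalled ones (odds ratios 0.590 and 0.296). After quantile normalization these were 0.353 and 0.376.

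**Figure D4:**
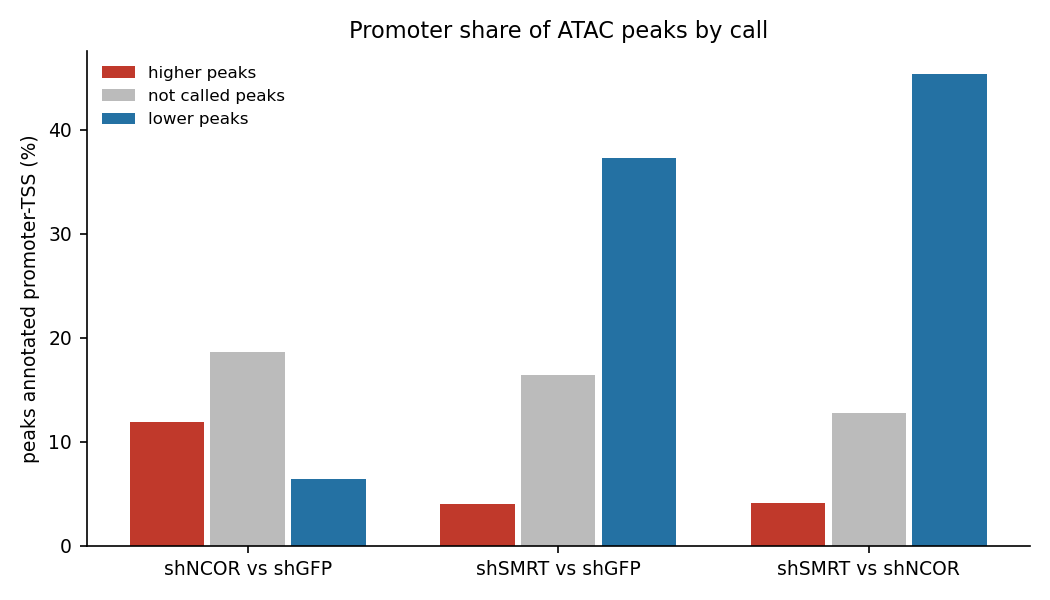
Percent of ATAC peaks annotated as promoter among higher (red), uncalled (grey) and lower (blue) peaks in each comparison. In shSMRT against shGFP, promoters were 37.3% of lower and 3.99% of higher peaks, on the authors' scaling.

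Peaks within 50 kb of interferon-stimulated genes were lower in shNCOR, with 18 of 78 called lower and 0 higher (camera, adjusted p = 1.99e-07, and 0.0157 with an estimated correlation). Peaks near osteoclast genes were higher in shNCOR (15 of 95 higher, 1 lower, adjusted p = 0.00407, and adjusted p = 0.144 with an estimated correlation), as were those near LXR target genes (adjusted p = 0.0177, and adjusted p = 0.144 with an estimated correlation) and lysosome genes (adjusted p = 0.0304, and adjusted p = 0.665 with an estimated correlation). Without shNCOR replicate 2 the LXR and lysosome calls ended (adjusted p = 0.0824 and 0.148), and so they did under quantile normalization (0.0683 and 0.25). The lysosome call also ended without shGFP replicate 2 or 3 (0.0875 and 0.0563). In shSMRT, peaks near alternative activation genes were higher (11 of 105 higher and 3 lower, adjusted p = 0.000636, and adjusted p = 0.166 with an estimated correlation). Peaks near histone genes (13 of 19 lower, adjusted p = 4.59e-06, and adjusted p = 0.181 with an estimated correlation) and near stress response genes (22 of 67 lower, adjusted p = 6.98e-05, and adjusted p = 0.181 with an estimated correlation) were lower. So were peaks near fatty acid genes (adjusted p = 0.000685, and adjusted p = 0.166 with an estimated correlation), cholesterol genes (adjusted p = 0.000697, and adjusted p = 0.181 with an estimated correlation) and hypoxia genes (adjusted p = 0.000727, and adjusted p = 0.181 with an estimated correlation). Peaks near osteoclast genes were called higher in shSMRT (10 higher and 4 lower of 95), and those near proliferation and oxidative phosphorylation genes lower. These 3 calls (adjusted p = 0.0478, 0.0478 and 0.0478, and adjusted p = 0.181, 0.381 and 0.307 with an estimated correlation) ended without most single libraries. They also ended with the replicate number as a block (adjusted p = 0.0551, 0.06 and 0.0502). The proliferation and oxidative phosphorylation calls ended under quantile normalization too (adjusted p = 0.254 and 0.0944). Peaks near neutrophil and mast cell genes (adjusted p = 0.897 in shNCOR and 0.569 in shSMRT), lymphocyte genes (0.42 and 0.0696) and fibroblast and epithelial genes (0.87 and 0.0927) were not called, although the last passed in shSMRT without shGFP replicate 2 (0.044).

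Lists whose peaks were not called include several that were called in RNA. In shSMRT the lists not called were, besides the markers of other cell types, the corepressor complex subunits (2 higher and 3 lower of 34, adjusted p = 0.874), the LXR target genes (6 higher and 17 lower of 91, adjusted p = 0.778) and the NF-kB and AP-1 inflammatory genes (20 higher and 27 lower of 182, adjusted p = 0.316). Also not called were the interferon-stimulated genes (3 higher and 13 lower of 78, adjusted p = 0.527), the PPAR target genes (6 higher and 5 lower of 63, adjusted p = 0.562) and the monocyte and macrophage identity genes (6 higher and 14 lower of 162, adjusted p = 0.774). The same holds for the lysosome genes (2 higher and 13 lower of 107, adjusted p = 0.41), the dendritic cell and MHC class II genes (8 higher and 6 lower of 65, adjusted p = 0.232) and the antioxidant and NRF2 target genes (3 higher and 12 lower of 63, adjusted p = 0.0927). Nor was a call made for the complement and phagocytosis genes (6 higher and 0 lower of 87, adjusted p = 0.0903) and the ribosomal protein and RNA quality genes (2 higher and 4 lower of 41, adjusted p = 0.632). In shNCOR they were the corepressor complex subunits (4 higher and 1 lower of 34, adjusted p = 0.305), fatty acid synthesis and desaturation (0 higher and 1 lower of 59, adjusted p = 0.42) and cholesterol synthesis and uptake (0 higher and 0 lower of 55, adjusted p = 0.635). Also not called were the NF-kB and AP-1 inflammatory genes (21 higher and 8 lower of 182, adjusted p = 0.57), the IL-4 and alternative activation genes (10 higher and 4 lower of 105, adjusted p = 0.752) and the PPAR target genes (9 higher and 2 lower of 63, adjusted p = 0.303). The same holds for the monocyte and macrophage identity genes (9 higher and 8 lower of 162, adjusted p = 0.517), the dendritic cell and MHC class II genes (5 higher and 3 lower of 65, adjusted p = 0.878) and the proliferation genes (0 higher and 0 lower of 57, adjusted p = 0.752). Nor was a call made for the integrated stress and unfolded protein response (1 higher and 0 lower of 67, adjusted p = 0.812), the hypoxia and glycolysis genes (5 higher and 1 lower of 78, adjusted p = 0.752) and the oxidative phosphorylation genes (2 higher and 3 lower of 51, adjusted p = 0.752). Uncalled too were the antioxidant and NRF2 target genes (4 higher and 1 lower of 63, adjusted p = 0.246), the complement and phagocytosis genes (8 higher and 5 lower of 87, adjusted p = 0.305) and the ribosomal protein and RNA quality genes (2 higher and 0 lower of 41, adjusted p = 0.132). Not called either were the replication-dependent histone genes (0 higher and 1 lower of 19, adjusted p = 0.752). The ribosomal list passed in shNCOR without shNCOR replicate 3 (0.0289).

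Between the knockdowns, peaks near 10 gene lists were lower in shSMRT than in shNCOR and peaks near 3 were higher, none of them called with an estimated correlation. Lower were peaks near histone (14 of 19 lower and 0 higher, adjusted p = 2.82e-06, and adjusted p = 0.106 with an estimated correlation) and fatty acid genes (25 of 59 lower and 1 higher, adjusted p = 7.93e-05, and adjusted p = 0.0675 with an estimated correlation). So were those near stress response genes (26 of 67 lower and 0 higher, adjusted p = 7.93e-05, and adjusted p = 0.106 with an estimated correlation) and cholesterol genes (25 of 55 lower and 1 higher, adjusted p = 0.000141, and adjusted p = 0.106 with an estimated correlation). Further lower lists were antioxidant (21 of 63 lower and 1 higher, adjusted p = 0.00347, and adjusted p = 0.193 with an estimated correlation) and lysosome genes (29 of 107 lower and 0 higher, adjusted p = 0.00348, and adjusted p = 0.229 with an estimated correlation). Peaks near hypoxia (27 of 78 lower and 1 higher, adjusted p = 0.0072, and adjusted p = 0.193 with an estimated correlation) and LXR target genes (30 of 91 lower and 4 higher, adjusted p = 0.0118, and adjusted p = 0.106 with an estimated correlation) were lower too. The last lower lists were proliferation (23 of 57 lower and 1 higher, adjusted p = 0.0191, and adjusted p = 0.272 with an estimated correlation) and ribosomal genes (14 of 41 lower and 1 higher, adjusted p = 0.0404, and adjusted p = 0.272 with an estimated correlation). Under quantile normalization 6 of these calls ended, those on LXR target (adjusted p = 0.0577), lysosome (0.4), proliferation (0.337), hypoxia (0.306), antioxidant (0.225) and ribosomal genes (0.337). The proliferation call also ended without shNCOR replicate 1 (0.0605), and the ribosomal call without shNCOR replicate 1 (0.0934) or 2 (0.101) or shSMRT replicate 1 (0.0639). Higher were peaks near interferon-stimulated (14 of 78 higher and 3 lower, adjusted p = 0.000303, and adjusted p = 0.0675 with an estimated correlation), alternative activation (9 of 105 higher and 4 lower, adjusted p = 0.00348, and adjusted p = 0.106 with an estimated correlation) and lymphocyte genes (2 of 15 higher and 0 lower, adjusted p = 0.00721, and adjusted p = 0.106 with an estimated correlation).

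Relative to uncalled genes, genes higher in RNA had more accessible peaks and genes lower in RNA less accessible ones. Genes higher in RNA in shNCOR (1777 genes with a peak within 50 kb) had a mean peak change 0.08 above that of uncalled genes on the log2 scale, and genes lower in RNA (2020) one of -0.09 relative to them. A called higher peak lay near 24.2% of genes higher in RNA and 8.61% of uncalled genes. In shSMRT the differences were 0.10 for 2490 higher and -0.05 for 3110 lower genes, and in shSMRT against shNCOR 0.12 and -0.07. The mean peak change itself was below 0 at the genes higher in RNA in these comparisons (-0.03 in shSMRT and -0.06 against shNCOR). In shSMRT a higher peak lay near 20.1% and a lower peak near 27.6% of them (8.07% and 30.1% of uncalled genes). Against shNCOR these shares were 16.5% and 47.2% (6.38% and 54.0% of uncalled genes). Each of the 6 differences in mean had p = 1e-05 in a two-sided permutation test over genes, the smallest that 100000 permutations can give (adjusted over the 6 tests also 1e-05). Genes are not independent replicates, and the SD over genes in shNCOR was 0.20 for higher genes.

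Both knockdowns shared 924 higher and 646 lower peaks, among them the lower Tmem176b promoter and the higher Atp6v0d2 promoter, where independent lists would share 161 and 224. A further 95 peaks were called in opposite directions. The covariance of fold changes was 0.0789, against 0.0279 simulated, and the correlation 0.427 against 0.4999. Unchanged groups shared 0 calls, which again is no measure of sharing through the controls, as such groups have almost no calls. Part of the excess may come from the shared controls.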

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

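The test of a raised control level was chosen after its result was seen, as was the use of quantile normalization to judge the share of lower peaks, and the other tests here were set out before their results were seen. The knockdowns differed from each other, by the direct contrast between them, in 8 gene lists that passed under both the preset and the estimated correlation. The median log2 difference of shSMRT minus shNCOR was 0.59 for NF-kB and AP-1 inflammatory genes, 1.23 for interferon-stimulated genes, 0.67 for IL-4 and alternative activation genes, 0.30 for monocyte and macrophage identity genes, 0.62 for osteoclast genes, 1.00 for dendritic cell and MHC class II genes, -0.15 for proliferation genes, 0.42 for complement and phagocytosis genes. Genes called in opposite directions by the knockdowns, among those with the largest changes, were Opcml (difference -2.13), Car2 (difference -2.70), Angptl2 (difference 3.34), Rgs16 (difference 2.89), Gas6 (difference -1.72).

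Interferon-stimulated genes were lower in shNCOR than in shGFP, 29 of 29 members. A raised level in the shGFP libraries alone is argued against by the shSMRT libraries, which stood 1.23 above shNCOR (median log2 difference). The authors' scaling is argued against too, since the median log2 fold change of all tested genes in shNCOR was 0.002, against -1.54 for the list. After quantile normalization 29 members were still called lower. That step moved the median of all genes only to 0.014, so it could hardly have ended these calls and adds little. A difference between the separately infected cell populations other than Ncor1 itself stays open and untested, as does a smaller rise of the control, since shSMRT lay -0.43 from shGFP. ATAC peaks near these genes were also lower in shNCOR (18 of 78 called lower).

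More ATAC peaks were lower than higher in shSMRT against shGFP, often promoters, and weak peaks are argued against as the cause, since the share of lower calls was 69.0% with the stricter filter. The excess was one of small changes, as 1627 peaks were higher and 497 lower by at least 1 on the log2 scale. The lower share of reads in peaks in shSMRT cannot be told apart from a change in the cells. Centring each library on its median left 57.3% of calls lower, above the 55% set beforehand as the bound that would argue against this explanation. That bound was passed, but the test was a poor one, because centring moved the median log2 fold change only from -0.092 to -0.081. Quantile normalization, brought in after that result was seen, left 43.3% lower, but it would also remove a real change across promoters.

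Other splits of the 6 libraries in each comparison are too few for a share under 0.05, since 10 splits allow no share under 0.1. In RNA the real split called 3705 for shNCOR against shGFP, 6130 for shSMRT against shGFP and 5449 for shSMRT against shNCOR, and in ATAC 4362 for shNCOR against shGFP, 10570 for shSMRT against shGFP and 11134 for shSMRT against shNCOR, in fits on the 6 libraries alone. The highest of the other splits called 0 in each, and 1 of the 10 splits, the real one, gave a result as large.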

How the results depend on the processing

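The voom and exon length settings were chosen after seeing the data. A fold threshold of 1 on the log2 scale left, higher and lower in turn, 52 and 113 genes in shNCOR, 156 and 40 in shSMRT and 188 and 27 between the knockdowns, and 421 and 856, 1627 and 497 and 1722 and 339 ATAC peaks, by construction. Quantile normalization left 3358 peaks lower in shSMRT than in shGFP and 2401 lower than in shNCOR, and the stricter filter 2367 higher than in shNCOR, with fewer peaks tested. With an estimated correlation the RNA lists called went from 9 to 3 in shNCOR, 15 to 4 in shSMRT and 13 to 8 between them, and the ATAC lists from 4 to 1, 9 to 0 and 13 to 0. Quantile normalization left 2 ATAC lists in shNCOR and 7 between the knockdowns. Leaving out single libraries gave 1228 to 2457 higher and 1156 to 2131 lower peaks and 2 to 5 ATAC lists in shNCOR, and 2710 to 6247 lower peaks in shSMRT. Apart from the fold threshold and the steps named, the cause was not tested. Other counts of calls stayed within 1.5 times. The larger side changed, however, under quantile normalization in RNA shNCOR (2107 higher and 2025 lower) and in all ATAC comparisons (1643 higher and 2020 lower in shNCOR, 4390 higher and 3358 lower in shSMRT, 3550 higher and 2401 lower between them). It also changed in RNA shNCOR without the exon length trend (2243 higher and 2073 lower), in ATAC shNCOR with median centring and without shGFP replicate 2 or shNCOR replicate 3, and at the fold threshold in RNA shSMRT, RNA between the knockdowns and every ATAC comparison. No called gene named by the rule changed sign, nor did any of the 5 most raised and 5 most lowered peaks per knockdown. Peaks nearest to start sites, and genes chosen only after their values were seen, were not followed across the settings. Of the called lists only the ATAC osteoclast list in shSMRT changed sign, with a median of 0.012 that became -0.015 without shGFP replicate 2 and -0.012 without shSMRT replicate 2, where its call ended. Voom on recovered reads called 2036 higher and 2261 lower genes in shNCOR and 2732 and 3428 in shSMRT. Of the named genes and lists under all settings, 96 gene and 97 list values lost their call and 2 and 10 gained one.

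Same-numbered libraries correlated weakly (-0.0602 to 0.105 for deviations from the group mean), although 6 of 9 RNA and 0 of 9 ATAC libraries correlated best with their own number, so a weak pairing in RNA is not excluded. With the replicate block, RNA calls were 1996 and 2259 in shNCOR and 2686 and 3470 in shSMRT, and ATAC calls 2201 and 2047 and 3474 and 5172. A test on all rows was not run, since no gene symbol repeats, nor were the planned count models on recovered reads. In simulated data fewer small changes were recovered in ATAC than in RNA, a difference whose cause was not tested.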

Other observations

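The 15 gene families here, taken by symbol, were chosen after the data were seen, so their camera p-values are descriptive only. Not all of the 15 are described. Among the others, C-type lectins were called higher in shSMRT (camera, adjusted p = 3.72e-05, and 0.0752 with an estimated correlation). They were also called higher in shNCOR (adjusted p = 0.0288, and 0.368 with an estimated correlation). Integrins were called higher in shSMRT (adjusted p = 0.000657, and 0.0752 with an estimated correlation) and not called in shNCOR (0.126). The Schlafen family was called lower in shNCOR (adjusted p = 0.0288, and 0.368 with an estimated correlation), and kinesins in neither knockdown. The windows were also chosen after the data were seen, while the test of a gained segment in them was set out before its result was seen. MHC class I genes were lower in shNCOR (0 of 18 higher and 14 lower, adjusted p = 5.95e-09, and 0.0972 with an estimated correlation), with H2-T23 at -1.44 ± 0.05. Proteasome subunits were lower in shNCOR (0 of 39 higher and 12 lower, adjusted p = 0.0096, and 0.635 with an estimated correlation), and the largest decreases were those of Psmb8 (-0.66 ± 0.07), Psmb10 (-0.37 ± 0.07) and Psmb9 (-0.33 ± 0.05). They were lower in shSMRT too (0 of 39 higher and 33 lower, adjusted p = 6.95e-08, and 0.271 with an estimated correlation). Vacuolar ATPase subunits, which acidify lysosomes and the osteoclast border, were higher in shNCOR (15 of 18 higher and 0 lower, adjusted p = 8.65e-08, and 0.176 with an estimated correlation) and in shSMRT (13 of 18 higher and 0 lower, adjusted p = 1.2e-06, and 0.132 with an estimated correlation), with Atp6v1b2 at 0.51 ± 0.04 and 1.05 ± 0.04.

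In shSMRT, chemokine ligands and receptors were higher (14 of 19 higher and 2 lower, adjusted p = 1.83e-06, and 0.0392 with an estimated correlation), with Ccl9 at 1.64 ± 0.04 and Cxcl14 at 1.67 ± 0.04. Cathepsins were higher (10 of 11 higher and 0 lower, adjusted p = 6.95e-08, and 0.0815 with an estimated correlation), Ctsk at 2.39 ± 0.11. Mitochondrial ribosomal proteins (0 of 78 higher and 60 lower, adjusted p = 2.22e-09, and 0.228 with an estimated correlation) and aminoacyl-tRNA synthetases (0 of 18 higher and 17 lower, adjusted p = 6.95e-08, and 0.0752 with an estimated correlation) were lower, with Mrpl40 at -0.56 ± 0.04 and Gars at -0.60 ± 0.03. The families were not retested with the exon length trend removed, although fold changes in shSMRT rose with exon length (Spearman rho 0.160). In shNCOR the synthetases were lower as well (0 of 18 higher and 14 lower, adjusted p = 1.19e-05, and 0.176 with an estimated correlation), whereas mitochondrial ribosomal proteins (6 of 78 higher and 5 lower, adjusted p = 0.933, and 0.947 with an estimated correlation), cathepsins (5 of 11 higher and 2 lower, adjusted p = 0.169, and 0.635 with an estimated correlation) and chemokine genes (6 of 19 higher and 7 lower, adjusted p = 0.944, and 0.947 with an estimated correlation) were not called.

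Among 731 windows of 3 Mb with at least 10 tested peaks, that with the highest median peak change in shNCOR was chr14, 15 to 18 Mb, which holds Rarb (22 peaks, median log2 fold change 1.21, 14 called higher and 0 lower). In shSMRT it was chr8, 54 to 57 Mb, which holds Hpgd and Vegfc (19 peaks, median 1.19, 11 called higher and 0 lower). A gained chromosome segment might raise all peaks of a window alike. In shSMRT 31.6% of the window's peaks lay below 0.2 on the log2 scale, which argues against it for that window as a whole, and of the 5 genes tested in RNA there Hpgd (5.25 ± 0.09) and Vegfc (1.99 ± 0.09) were higher, Cep44 (-0.23 ± 0.08) and Spcs3 (-0.16 ± 0.03) lower and Fbxo8 (-0.05 ± 0.06) not called. In shNCOR 18.2% did, between the bounds set beforehand, so a gain cannot be told apart from opening around Rarb there, although the RNA of Top2b (0.08 ± 0.04), Ngly1 (-0.08 ± 0.07) and Oxsm (0.07 ± 0.07) in the window was not called.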
